A study of Homo sapiens with 28 samples.

How the data were processed

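Gene expression was measured in human T cell clones from 2 healthy donors on Affymetrix Human Genome U133 Plus 2.0 arrays. The 14 clones were 4 conventional CD4 clones, 6 NKT clones and 4 clones that stained for CD1d loaded with α-galactosylceramide but lacked the Vα24 chain (called Va24neg here). Each clone gave 2 arrays, 28 in all: resting cells, 18 days after their last stimulation, and stimulated cells, 3 days after stimulation with irradiated allogeneic blood cells, irradiated EBV-transformed B cells, PHA and IL-2. CD4 and Va24neg clones came in equal numbers from both donors (2 and 2), and NKT clones in the numbers 4 and 2. Every array was assigned to its group, donor and clone from its own labels.

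The deposited values, 1 per probe set and array, are intensity on a linear scale. The mean of each array after trimming 2 percent of the values at each end lay between 500.05 and 500.09, so the arrays had been scaled to a common level. The summarization method is not given in the sources used here. Values ran from 0.0673 to 67983.2, and array medians of the log2 values from 6.219 to 6.627, a gap of 0.408. Below a gap of 0.5 the values were to be used as deposited, and so they were, as log2 of the value plus 16. No array was left out, and no columns were identical; the correlation of log2 values between arrays of a group lay between 0.937 and 0.972.

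Of 54675 probe sets, 62 were controls, 41091 carried 1 gene symbol, 1801 several and 11721 none; only those with 1 symbol were used. XIST, TSIX and genes of the Y chromosome (59 probe sets) were removed before any test. A gene with several probe sets was represented by the probe set with the highest mean log2 value over all arrays. This gave 19740 genes, of which 13634 had a log2 value above the median of all probe sets of the array in at least 4 arrays and were tested. Some genes chosen beforehand are not reported here. CD8A and CD8B stayed below that filter, so that only their intensities are given.

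Genes were tested with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 6 groups and donor as an additive term (21 residual degrees of freedom, 2.68 added by moderation). Contrasts gave 9 comparisons of 2 groups and 3 differences of the stimulation response between cell types. The Benjamini-Hochberg correction was made within each comparison, and genes with an adjusted p under 0.05 were called. Differences are on the scale of log2 of the value plus 16, which understates the change of genes near the floor, with the standard error (SE) of the fit, and intensities are mean ± SD over clones. P-values measure the spread between clones of 2 donors, so they do not extend to other donors. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.

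The 22 gene lists were each tested in the 12 comparisons with camera at a preset correlation of 0.01, with the correction over all 264 tests, and again with the correlation estimated. The 18 T cell lists were the innate-like T cell programme, NK cell receptors, cytotoxic effectors, naive and central memory, Th1, Th2, Th17, B cell help, regulatory T cell, secreted cytokines and chemokines, chemokine receptors, activation and costimulation, cell cycle, glycolysis, cholesterol synthesis, interferon response, lineage and T cell receptor complex, and SLAM family. The other 4 held markers of B cells (including feeder lines), monocytes, natural killer cells, and red cells with platelets. Of the 10 natural killer genes 8 were also in a T cell list, so that list cannot part natural killer cells from expression by the clones. For those 4 the mean log2 value per array was also compared by exact permutation, with the correction over 28 tests. Groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. By that rule, the text names up to 10 genes in each direction with the largest differences among called genes without overlap between the arrays of the 2 groups (5 for a difference of responses). It also names the strongest called members of the lists, and ZBTB16, KLRB1, CD4, CD8A, CD8B, TBX21, GATA3, IFNG, IL4, CCR7 and MKI67 in any case. Genes that follow a donor's genotype are not named.

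Clone numbers pair the resting and stimulated arrays. After removal of the group means, the correlation between the arrays of a clone was above 0.1 in 14 of 14 clones (0.174 to 0.362), and the closest array in the other state was from the same clone in 14 of 14. A clone block was an alternative and not part of the model; its consensus correlation was 0.163. The model was tested on simulated data with 200 changed genes among 13634 and the same group sizes, 3 draws per comparison. Of genes changed by 1 on the log2 scale, it recovered 52, 60.7 and 56.3 percent for stimulated against resting CD4, NKT and Va24neg clones. The shares were 58.3, 51.7 and 62.3 percent for NKT against CD4, Va24neg against CD4 and NKT against Va24neg in the resting state, and 52.7, 52.7 and 58 percent in the stimulated state. Of genes changed by 2, the shares in the same order were 90.3, 93.7 and 88.3, then 91, 87 and 91.3, then 91, 86.7 and 93.3 percent. Between 6 and 8.67 calls per draw were false, and 0 had the wrong sign by limma. The noise was drawn independently for each array, without the pairing by clone, and the 3 differences of responses were not simulated. The shares hold for 200 changed genes picked at random. They do not carry over to comparisons with few calls or to genes that vary widely between clones. For the list test, 0 of 19 simulated unchanged lists were called by camera. That result does not carry over to real lists whose members vary together. Of 264 tests on the real lists, 58 were called at the preset correlation, and 14 of these also with the correlation estimated.

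Alternatives covered quantile normalization, pseudocounts of 1 and 64, no filter and a filter at the 70th percentile, other ways to choose a probe set, no donor term, each donor alone, and only the arrays compared. They also covered clone as a random or fixed block, a trended and robust prior, other list tests, and leaving out each clone. Added after seeing the data were a fit without the resting array of NKT clone A4, a fit with the actin 3'/5' ratio as a covariate, and the B cell score without POU2AF1.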

Results

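ZBTB16 encodes PLZF, the transcription factor that drives the innate-like programme of NKT cells, and is given first. In resting clones its intensity was 3380 ± 1510 in NKT (n = 6), 1620 ± 678 in Va24neg (n = 4) and 1040 ± 1580 in CD4 clones (n = 4). Among the CD4 clones 1 stood at 3420 and the lowest at 160. Stimulated clones held 2300 ± 582, 995 ± 655 and 353 ± 543. Between the paired arrays ZBTB16 was lower after stimulation in 4 of 6 NKT, 4 of 4 Va24neg and 4 of 4 CD4 clones. By limma the differences were -0.45 in NKT (adjusted p = 0.46), -0.80 in Va24neg (0.34, or 0.02 with clone as a fixed block) and -1.45 in CD4 clones (0.051, or 0.00018). Against stimulated CD4 clones, ZBTB16 was higher in NKT clones by 3.45 (SE 0.58, adjusted p = 0.0075) and in Va24neg clones by 2.27 (SE 0.63, adjusted p = 0.0045). The NKT call was lost without CD4 clone A4 (2.89, adjusted p = 0.067), in donor A only (2.69, adjusted p = 0.58) and with only the arrays compared (3.51, adjusted p = 0.32), and the Va24neg call in donor A only (1.97, adjusted p = 0.18). Resting differences from CD4 were 2.44 (SE 0.58, adjusted p = 0.32) and 1.62 (SE 0.63, adjusted p = 1) and were not called. They became 3.34 (adjusted p = 1.4e-05) and 2.44 (adjusted p = 0.0073) without CD4 clone A1. That clone held the highest ZBTB16 of the CD4 clones, so leaving it out raises these differences by construction. The 2 adjusted p-values of that limma fit are therefore no independent evidence. NKT exceeded Va24neg clones by 0.82 at rest (SE 0.58, adjusted p = 1) and by 1.17 after stimulation (SE 0.58, adjusted p = 0.099), also not called.

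**Figure D1:**
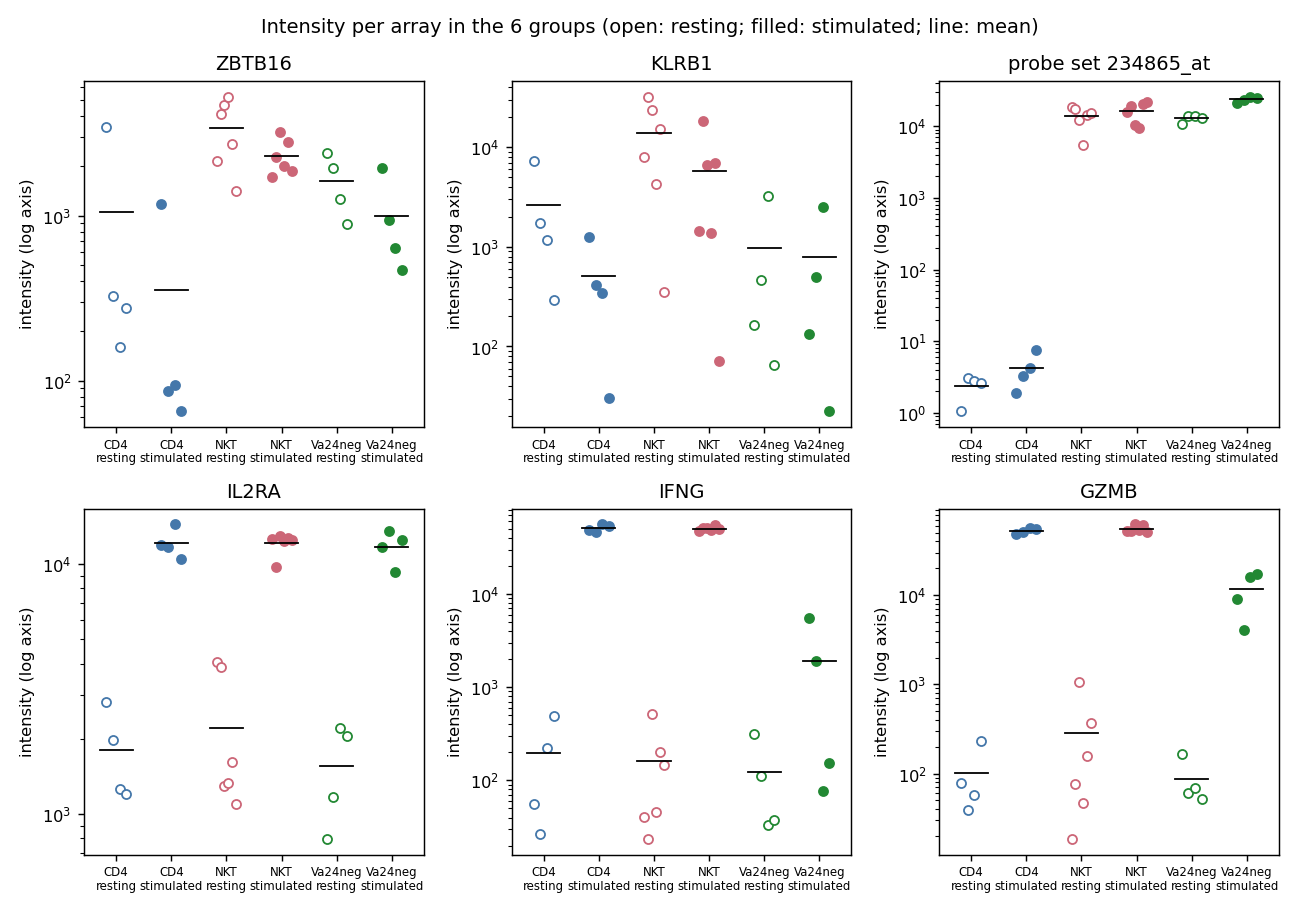
Intensity per array of ZBTB16, KLRB1, the probe set annotated to IL23A, IL2RA, IFNG and GZMB in the 6 groups, on a log axis. Open symbols are resting and filled symbols stimulated clones.

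KLRB1 (CD161, a lectin-like receptor of innate-like T cells) varied widely between clones. It measured 14000 ± 12200 in resting NKT, 2630 ± 3190 in CD4 and 985 ± 1520 in Va24neg clones, with single NKT clones from 353 to 32100. Between the paired arrays KLRB1 was lower after stimulation in 6 of 6 NKT, 4 of 4 CD4 and 3 of 4 Va24neg clones. The differences were -1.65 in NKT (adjusted p = 0.24, or 5.4e-06 with clone as a fixed block), -2.25 in CD4 (0.2, or 2.4e-06) and -0.41 in Va24neg clones (0.86, or 0.21). The CD4 coreceptor transcript was at 3460 ± 473 in resting CD4 and 3430 ± 447 in Va24neg clones. NKT clones had 1670 ± 1380: A14 and A22 were at 21 and 16.1 and the other 4 between 1530 and 2970. CD8A lay near the floor in every group (from 6.20 ± 3.85 in resting CD4 to 14.0 ± 13.4 in stimulated NKT clones), and CD8B ranged from 17.5 ± 6.83 to 40.8 ± 31.0. GATA3, a Th2 regulator, was abundant at rest (12900 ± 2550 in CD4, 15400 ± 4270 in NKT, 15100 ± 3190 in Va24neg clones). CCR7, a lymph node homing receptor, was low (128 ± 46.6, 80.9 ± 32.6 and 118 ± 36.9).

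Between resting NKT and CD4 clones 1 of 13634 genes was called, with 770 at an unadjusted p under 0.05. The count ran from 1 to 8 when 1 clone was left out, with 8 without CD4 clone A1. The call was a probe set annotated to IL23A (the p19 subunit of interleukin 23). It was at 14000 ± 4710 in NKT (n = 6) and 2.37 ± 0.892 in CD4 clones (n = 4), a log2 difference of 9.53 (SE 0.24, adjusted p = 6.2e-19). Another probe set of the gene was at 316 ± 58.6 in NKT, 383 ± 82.6 in Va24neg and 336 ± 15.3 in CD4 clones at rest, so the value is not read as a level of IL23A transcript. IL4 (1.98, SE 0.63, adjusted p = 0.56) and KLRB1 (2.04, SE 1.38, adjusted p = 0.98) were not called. TBX21 (0.57, SE 0.53, adjusted p = 1) and IFNG (-0.29, SE 0.90, adjusted p = 1) were not called either, and none was called among CD4, GATA3, CCR7 and MKI67. The innate-like T cell programme shifted upward in NKT clones (median 0.372, 0 of 14 members called, adjusted p = 0.000235, adjusted p = 0.06 with an estimated correlation). Adjusted over the list alone, 2 members rose. Glycolysis shifted downward (median -0.141, 0 of 17 called, adjusted p = 0.0299, adjusted p = 0.53 with an estimated correlation). Here 1 member fell when adjusted over the list alone.

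Va24neg clones also differed from resting CD4 clones in 1 called gene, the same probe set of IL23A, with 571 genes at an unadjusted p under 0.05. It was 1 to 5 genes when 1 clone was left out, with 5 without CD4 clone A1, and 20 in donor B only. The probe set was at 13000 ± 1410 in Va24neg clones (n = 4), a difference of 9.46 (SE 0.26, adjusted p = 5.4e-18). Naive and central memory genes shifted downward (median -0.443, 0 of 15 called, adjusted p = 0.0112, adjusted p = 0.293 with an estimated correlation), as did glycolysis (median -0.0944, 0 of 17 called, adjusted p = 0.00783, adjusted p = 0.369 with an estimated correlation). Interferon response genes shifted upward (median 0.199, 0 of 19 called, adjusted p = 0.0329, adjusted p = 0.614 with an estimated correlation). Adjusted over the list alone, 0 members of these 3 lists were called by limma.

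Between resting NKT and Va24neg clones, KLRB1 had the largest difference of the genes named throughout (3.96, SE 1.38, adjusted p = 0.73), with 14000 ± 12200 against 985 ± 1520. limma called 0 of 13634 genes, with 703 at an unadjusted p under 0.05. The innate-like T cell programme shifted upward in NKT clones (median 0.554, 0 of 14 called, adjusted p = 0.00184, adjusted p = 0.0975 with an estimated correlation).

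Stimulated CD4 clones raised cytokine genes from near the floor to among the highest intensities on the array. IL3, a growth factor for blood cell precursors, rose from 9.35 ± 5.64 to 52400 ± 3150 (log2 difference 11.04, SE 0.17, adjusted p = 2.6e-24, n = 4 per group). CCL1 (11.02, SE 0.45), IL4 (9.80, SE 0.69), CXCL8 (9.45, SE 0.56) and IL5 (9.20, SE 1.04) followed. Among receptors and regulators, the largest increases were in the T cell activation receptor CRTAM (10.07, SE 0.76), the inhibitory ligand CD200 (9.67, SE 0.23), the kinase-like regulator TRIB1 (10.08, SE 0.42), and the transcription factors NR4A3 (9.71, SE 0.32) and ZBED2 (9.40, SE 0.55). Interferon gamma (IFNG) rose from 198 ± 211 to 51000 ± 4260, its regulator TBX21 from 501 ± 314 to 8950 ± 1630, and granzyme B (GZMB) by 9.06 (SE 0.68). The largest decreases were in C16orf54 (-8.66, SE 0.37), TXNIP (-7.14, SE 0.21; a brake on glucose uptake), SYNE1 (-6.96, SE 0.72), RIPOR2 (-6.96, SE 0.40), and GPR155 (-6.83, SE 0.43). They were followed by AKTIP (-6.72, SE 0.39), GIMAP4 (-6.64, SE 0.52), ACAP1 (-6.44, SE 0.45), CCDC69 (-6.34, SE 0.45) and PTPRCAP (-6.30, SE 0.33). The quiescence factor KLF2 fell by 6.21 (SE 0.34). The CD4 transcript itself fell from 3460 ± 473 to 467 ± 129 (-2.88, SE 1.09, adjusted p = 0.025). Of 13634 genes 8325 were called, 3127 higher and 5198 lower, and 5809 of them changed at least 2-fold. Array measures moved with stimulation too: in CD4 clones the actin 3'/5' ratio went from 2.54 ± 0.197 to 4.75 ± 0.17, the log2 value of ribosomal RNA probes from 9.49 ± 0.0741 to 10.3 ± 0.453 and that of spike-in controls from 11 ± 0.248 to 11.6 ± 0.0667.

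Gene lists gave the same picture of CD4 activation. Secreted cytokines and chemokines had a median of 7.77, and 17 of 20 members rose (adjusted p = 1.17e-08, adjusted p = 0.000946 with an estimated correlation). Activation and costimulation genes, with NR4A2 (7.95, SE 0.27) and TNFRSF9 (8.34, SE 0.54), had a median of 2.87 with 16 of 19 higher (adjusted p = 1.97e-08, adjusted p = 0.000165 with an estimated correlation). B cell help genes, with IL21 (9.00, SE 0.66) and POU2AF1 (6.54, SE 0.58), had a median of 3.55 with 7 of 9 higher (adjusted p = 0.00458, adjusted p = 0.0275 with an estimated correlation). When adjusted over the list alone, 1 member also fell. Th1 (median 2.70, 9 of 12 higher, adjusted p = 0.00195) and Th2 genes (median 1.00, 8 of 13 higher, adjusted p = 0.0241) moved up as well. For Th1, adjusted p = 0.389 with an estimated correlation, and for Th2, adjusted p = 0.548 with an estimated correlation. Interferon response genes, led by XAF1 (-4.48, SE 0.32) and OAS1 (-3.93, SE 0.32), moved down (median -1.73, 14 of 19 lower, adjusted p = 0.0107, adjusted p = 0.567 with an estimated correlation). When adjusted over the list alone, 15 fell.

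Other lists were not called in CD4 clones, although single members changed strongly. Cell cycle genes leaned downward (median -0.366, 3 rose and 11 fell of 27, adjusted p = 0.742), with TPX2 (-2.88, SE 0.37) and MCM5 (-2.76, SE 0.43) among those that fell. The proliferation marker MKI67 fell from 131 ± 21.9 to 78.0 ± 47.1. Th17 (median 3.71, adjusted p = 0.0684), SLAM family (0.779, 0.0661), glycolysis (0.306, 0.066, or 0.0286 with clone as a random block and adjusted p = 0.567 with an estimated correlation), regulatory T cell (0.949, 0.09), cytotoxic effector (0.508, 0.179) and cholesterol synthesis genes (0.0858, 0.313) had positive medians. Their strongest members included IL22 (8.96, SE 0.52), SLAMF1 (3.01, SE 0.22), PFKP (2.69, SE 0.13), CTLA4 (4.88, SE 0.82), FASLG (6.97, SE 0.49) and INSIG1 (3.87, SE 0.22). Chemokine receptors (median -2.04, adjusted p = 0.533), the lineage and T cell receptor complex list (-1.0, 0.677) and the innate-like T cell programme (-0.838, 0.997) had negative medians, with CCR2 (-4.51, SE 0.64) and LCK (-2.56, SE 0.14). For NK cell receptors the median was -0.0768 while the mean was 1.17 and the test pointed up (adjusted p = 0.269), since CRTAM and CD160 (5.85, SE 0.40) rose far. For naive and central memory genes the median was -0.111 and the mean -0.435 while the test pointed up (adjusted p = 0.701). Marker lists of other cells were not called: B cell (median 0.253, adjusted p = 0.416), monocyte (0.0272, 0.839; mean -0.537), natural killer (-0.388, 0.941; test up) and red cell and platelet (0.218, 0.484).

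NKT clones responded with nearly the same genes as CD4 clones. IL3 rose from 3.25 ± 3.04 to 49500 ± 9480 (11.32, SE 0.14, adjusted p = 1.2e-26, n = 6 per group), and IL2, the main T cell growth factor, from 66.4 ± 47.0 to 60800 ± 5080 (9.78, SE 0.39). CCL1 (10.93, SE 0.37), CD200 (9.92, SE 0.19), CRTAM (9.90, SE 0.62), TRIB1 (9.64, SE 0.35), CXCL8 (9.63, SE 0.46), NR4A3 (9.56, SE 0.26), IL5 (9.02, SE 0.85) and the stress response gene IER3 (8.88, SE 0.17) completed the largest increases. IFNG rose from 163 ± 188 to 50400 ± 2810 and IL4 from 262 ± 229 to 49700 ± 10100. AKTIP (-7.02, SE 0.32), C16orf54 (-6.69, SE 0.30), RIPOR2 (-6.66, SE 0.33), TXNIP (-6.43, SE 0.18), and the chemokine receptor CCR2 (-6.38, SE 0.52) fell most. NLRC3 (-6.04, SE 0.22), GIMAP4 (-5.93, SE 0.42), PTPRCAP (-5.88, SE 0.27), GIMAP6 (-5.87, SE 0.29) and HACD4 (-5.85, SE 0.26) also fell. Of 13634 genes 9042 were called, 3441 higher and 5601 lower, 5844 of them at least 2-fold. The actin ratio was 6.03 ± 8.15 in resting and 4.8 ± 0.871 in stimulated NKT clones, ribosomal RNA probes were at 9.99 ± 1.21 and 10.4 ± 0.742, and spike-in controls at 11.1 ± 0.32 and 11.6 ± 0.151. Resting clone A4 set the high resting mean of the actin ratio (22.6). The other resting NKT arrays lay between 1.7 and 3.27 and all stimulated ones between 3.68 and 5.95, so apart from A4 the ratio rose as in CD4 clones.

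In NKT clones the cytokine list had a median of 7.08 with 17 of 20 higher (adjusted p = 1.17e-08, adjusted p = 0.000946 with an estimated correlation). The activation list had 2.73 with 15 of 19 higher (adjusted p = 3.55e-08, adjusted p = 0.000165 with an estimated correlation). Th1 genes (median 2.27, 10 of 12 higher, adjusted p = 0.00104, adjusted p = 0.369 with an estimated correlation) and Th2 genes (median 1.17, 8 of 13 higher, adjusted p = 0.0222, adjusted p = 0.54 with an estimated correlation) moved up together. B cell help (median 2.20, 7 of 9 higher, adjusted p = 0.0116, adjusted p = 0.051 with an estimated correlation) and the SLAM family (median 0.909, 6 of 8 higher, adjusted p = 0.0376, adjusted p = 0.11 with an estimated correlation) rose. With clone as a random block the SLAM family had an adjusted p of 0.0648. The glycolysis list shifted upward at the preset correlation (median 0.259, 8 of 17 higher and 4 lower, adjusted p = 0.038, adjusted p = 0.552 with an estimated correlation). PKM (3.15, SE 0.15) and PFKP (3.05, SE 0.11) were highest, and ALDOC fell (-2.26, SE 0.33). Interferon response genes moved down (median -1.55, 14 of 19 lower, adjusted p = 0.00922, adjusted p = 0.567 with an estimated correlation). Here 16 fell when adjusted over the list alone.

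Va24neg clones answered stimulation with fewer and smaller changes. EGR1, an immediate early transcription factor, had the largest increase, from 51.7 ± 15.3 to 11500 ± 5480 (7.31, SE 0.49, adjusted p = 2.9e-11, n = 4 per group). IER3 (7.11, SE 0.21), GZMB (6.73, SE 0.68), TRIB1 (5.92, SE 0.42) and RGS16 (5.90, SE 0.42) followed. Further increases were in the costimulatory receptor TNFRSF18 (5.80, SE 0.50), CCL1 (5.59, SE 0.45), NR4A3 (5.56, SE 0.32), the phosphatase DUSP4 (5.27, SE 0.31) and the cystine transporter SLC7A11 (5.16, SE 0.42). IFNG rose only from 125 ± 132 to 1910 ± 2540, IL4 from 172 ± 88.5 to 1000 ± 528 and TBX21 from 459 ± 311 to 1910 ± 1800. The clones of donor A carried most of the rise in IFNG and TBX21: stimulated A4 and A7 had 5490 and 1920 of IFNG and 3240 and 3680 of TBX21. Stimulated B3 and B4 had 77.6 and 153 of IFNG and 356 and 363 of TBX21. The largest decreases were in GPR155 (-5.91, SE 0.43), RAP1GAP2 (-5.56, SE 0.54), PCYOX1 (-5.03, SE 0.46), and IDH1 (-4.84, SE 0.25). Next were C11orf21 (-4.77, SE 0.31), EPHA4 (-4.67, SE 0.54), DPYSL2 (-4.36, SE 0.34), ACADSB (-4.33, SE 0.35), EHMT2 (-4.29, SE 0.39) and VSIG1 (-4.19, SE 0.40). Of 13634 genes 5948 were called, 2091 higher and 3857 lower, 3229 of them at least 2-fold. In these clones the actin ratio went from 3.9 ± 0.419 to 2.04 ± 0.352, opposite to CD4 clones, ribosomal RNA probes from 9.37 ± 0.228 to 9.33 ± 0.23 and spike-in controls from 11 ± 0.164 to 11.3 ± 0.0794.

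Activation was the strongest list in Va24neg clones (median 2.32, 14 of 19 higher, adjusted p = 1.99e-10, adjusted p = 4.32e-05 with an estimated correlation), with the interleukin 2 receptor chain IL2RA up by 3.01 (SE 0.37). Secreted cytokines rose less (median 1.51, 10 of 20 higher, adjusted p = 7.21e-05, adjusted p = 0.0186 with an estimated correlation). Th1 (median 1.30, 7 of 12 higher, adjusted p = 0.0222, adjusted p = 0.563 with an estimated correlation) and regulatory T cell genes (median 0.879, 4 of 10 higher, adjusted p = 0.0243, adjusted p = 0.379 with an estimated correlation) shifted upward. Shifts of the same sign were called for glycolysis (median 0.384, 8 of 17 higher and 3 lower, adjusted p = 0.0111, adjusted p = 0.389 with an estimated correlation) and cholesterol synthesis (median 0.816, 7 of 11 higher and 1 lower, adjusted p = 0.0299, adjusted p = 0.162 with an estimated correlation). ALDOC fell among the glycolysis genes (-1.81, SE 0.40). Of the interferon response genes 10 of 19 fell (median -0.709, adjusted p = 0.216).

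The median over all genes was below 0 in the 3 stimulation responses as deposited (-0.187 in CD4, -0.182 in NKT and -0.191 in Va24neg clones) and closer to 0 after quantile normalization (-0.0298, -0.0396 and -0.0557). That scaling shift changed the share of calls that were higher from 37.6 to 44.2, from 38.1 to 44.4 and from 35.2 to 41.6 percent. Decreases thus stayed the majority of calls. Both scalings set the arrays to a common level, so neither can tell whether more genes fell than rose in absolute amount.

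**Figure D2:**
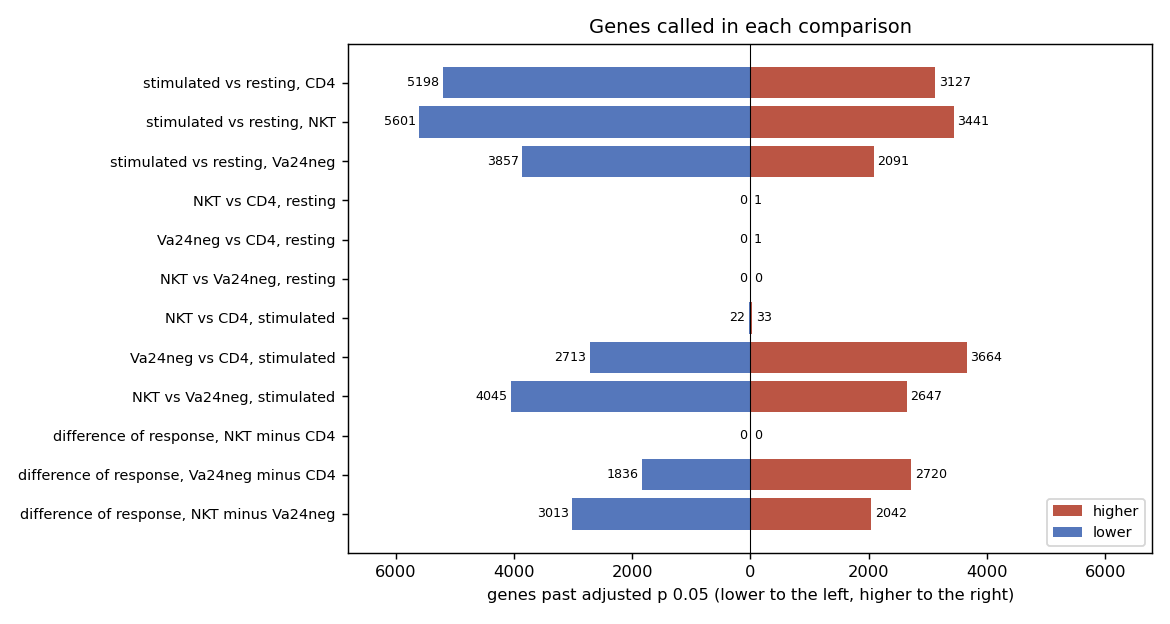
Number of genes higher and lower past an adjusted p of 0.05 in each of the 12 comparisons, out of 13634 tested.

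Stimulated NKT and CD4 clones differed in 55 genes, 33 higher and 22 lower in NKT clones, 26 of them at least 2-fold. The count ran from 10 to 304 when 1 clone was left out and was 2 with only the arrays compared, and 11 of 100 splits of these arrays, the real one included, gave 55 or more. Besides the probe set of IL23A (9.64, SE 0.24) and ZBTB16, NKT clones were higher in GOLIM4 (1.93, SE 0.40), C16orf54 (1.86, SE 0.34), GAB3 (1.46, SE 0.30) and ALDH6A1 (1.36, SE 0.21). Also higher were DUSP22 (1.04, SE 0.18), FAM117A (1.02, SE 0.22), LYST (0.95, SE 0.21) and LTB, a lymphoid tissue cytokine (4980 ± 2430 against 1760 ± 213; 1.33, SE 0.23, adjusted p = 0.0075). They were lower in SLC35D2 (-1.92, SE 0.32), the activin subunit INHBA (44.7 ± 17.4 against 194 ± 48.6; -1.83, SE 0.30, adjusted p = 0.0071), ZNF485 (-1.38, SE 0.29) and ROPN1L (-1.37, SE 0.30). Smaller decreases were in CCDC116 (-1.24, SE 0.24), HABP4 (-1.21, SE 0.23), the kinase PRKCA (-1.04, SE 0.22), ZKSCAN3 (-0.77, SE 0.15), ASXL2 (-0.56, SE 0.12) and RWDD4 (-0.51, SE 0.11). POU2AF1 was also lower (-2.53, SE 0.53, adjusted p = 0.036), while LCK was higher (0.79, SE 0.13, adjusted p = 0.0068). IFNG (50400 ± 2810 against 51000 ± 4260) and IL4 (49700 ± 10100 against 43100 ± 7490) were not called. Both lay near the highest value on any array (67983.2), and saturation was not tested. The innate-like T cell programme (median 0.219, 1 of 14 higher, adjusted p = 0.034, adjusted p = 0.379 with an estimated correlation) and NK cell receptors (median 0.266, 0 of 13 called, adjusted p = 0.047, adjusted p = 0.563 with an estimated correlation) leaned toward NKT clones, the latter with an adjusted p of 0.0551 with clone as a random block.

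Stimulated Va24neg clones stood far from stimulated CD4 clones, and IL3 had the largest difference on the scale used. It was at 2.18 ± 0.676 against 52400 ± 3150 (-11.49, SE 0.17, adjusted p = 1e-24, n = 4 per group). Since IL3 was near the floor in Va24neg clones, its log2 difference depended on the pseudocount (-14.03 with 1 and -9.63 with 64). IL22, a mucosal defence cytokine, was at 70.3 ± 26.6 against 45200 ± 8750 (-9.07, SE 0.52). IL2 was at 232 ± 220 against 64900 ± 1170 (-8.37, SE 0.48). CD200 (-8.56, SE 0.23), IL21 (-8.26, SE 0.66), SIPA1L2 (-7.92, SE 0.51), ZBTB32 (-7.01, SE 0.41), F5 (-6.99, SE 0.65), SLA (-6.75, SE 0.63) and POU2AF1 (-6.74, SE 0.58) were lower as well. IFNG was lower too, by a log2 difference of -6.31 (SE 0.99, adjusted p = 9.5e-06). Higher in Va24neg clones were the probe set of IL23A (10.21, SE 0.26), C16orf54 (6.86, SE 0.37), ASB2 (6.40, SE 0.65), the chemoattractant IL16 (17400 ± 2690 against 195 ± 20.7; 6.37, SE 0.14), EEIG1 (5.83, SE 0.26) and ARHGAP45 (5.78, SE 0.28). So were P2RY10 (5.61, SE 0.33), PIK3C2B (5.58, SE 0.40), CLEC2B (5.55, SE 0.35) and ARHGDIB (5.54, SE 0.37). In all 6377 genes were called, 3664 higher and 2713 lower, 3614 of them at least 2-fold. The same stimulated Va24neg arrays had an actin 3'/5' ratio of 2.04 ± 0.352 against 4.75 ± 0.17 in CD4 and 4.8 ± 0.871 in NKT clones, and a GAPDH ratio of 1.04 ± 0.0548 against 1.07 ± 0.0557 and 1.03 ± 0.088.

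Secreted cytokines as a list were lower in stimulated Va24neg than CD4 clones (median -4.92, 16 of 20 lower and 2 higher, adjusted p = 3.83e-07, adjusted p = 0.00277 with an estimated correlation). Th1 (median -1.67, 6 of 12 lower, adjusted p = 0.031, adjusted p = 0.567 with an estimated correlation), B cell help (median -3.06, 5 of 9 lower, adjusted p = 0.0299, adjusted p = 0.0937 with an estimated correlation) and SLAM family genes (median -1.09, 5 of 8 lower, adjusted p = 0.0354, adjusted p = 0.11 with an estimated correlation) shifted downward too. With clone as a random block the Th1 list had an adjusted p of 0.0592. The activation list shifted downward at the preset correlation (median -1.33, 8 of 19 lower and 2 higher, adjusted p = 0.0243, adjusted p = 0.071 with an estimated correlation), with NR4A2 lower (-5.91, SE 0.27) but EGR1 higher (4.23, SE 0.49). Interferon response genes were higher (median 1.41, 16 of 19 higher, adjusted p = 0.00139, adjusted p = 0.53 with an estimated correlation), led by OAS3 (3.34, SE 0.42) and XAF1 (2.85, SE 0.32). MAF, a regulator of IL4 and IL10, was higher (3.70, SE 0.54) and the chemokine receptor CXCR4 as well (3.74, SE 0.31), whereas the interleukin 18 receptor chain IL18R1 was lower (-4.09, SE 0.74).

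Stimulated NKT clones exceeded Va24neg clones in the same cytokines. IL3 (11.40, SE 0.15), CD200 (8.43, SE 0.21), IL2 (8.23, SE 0.44), and IL22 (8.09, SE 0.48) led. ZBTB32 (7.88, SE 0.38), SIPA1L2 (7.11, SE 0.47), SLA (6.71, SE 0.58), XIRP1 (6.69, SE 0.40), the NK receptor CD160 (6.64, SE 0.37) and NR4A2 (6.36, SE 0.24) came next. Lowest were IL16 (-6.34, SE 0.13), AKTIP (-5.77, SE 0.36), EEIG1 (-5.36, SE 0.24), P2RY10 (-5.36, SE 0.30) and ASB2 (-5.26, SE 0.59). They were followed downward by PRKACB (-5.10, SE 0.22), the detoxifying enzyme NQO1 (-5.09, SE 0.33), PTPRCAP (-5.01, SE 0.30), C16orf54 (-5.00, SE 0.34) and ARHGDIB (-4.99, SE 0.34). CCR7 was lower in NKT clones (88.2 ± 55.7 against 155 ± 13.4; -0.80, SE 0.31, adjusted p = 0.033). The comparison called 6692 genes, 2647 higher and 4045 lower, 3595 of them at least 2-fold. Cytokines (median 4.86, 17 of 20 higher, adjusted p = 1.47e-08, adjusted p = 0.000946 with an estimated correlation) and the SLAM family (median 1.32, 5 of 8 higher, adjusted p = 0.0105, adjusted p = 0.0472 with an estimated correlation) were called by both forms of the test. Th1 (median 1.78, adjusted p = 0.00951, adjusted p = 0.53 with an estimated correlation), Th2 (1.05, adjusted p = 0.0472, adjusted p = 0.567 with an estimated correlation) and B cell help (1.12, adjusted p = 0.0299, adjusted p = 0.0937 with an estimated correlation) were called only at the preset correlation. Activation (0.223, adjusted p = 0.0216, adjusted p = 0.06 with an estimated correlation) and, downward, the interferon response (-1.31, adjusted p = 0.00235, adjusted p = 0.548 with an estimated correlation) behaved alike.

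**Figure D3:**
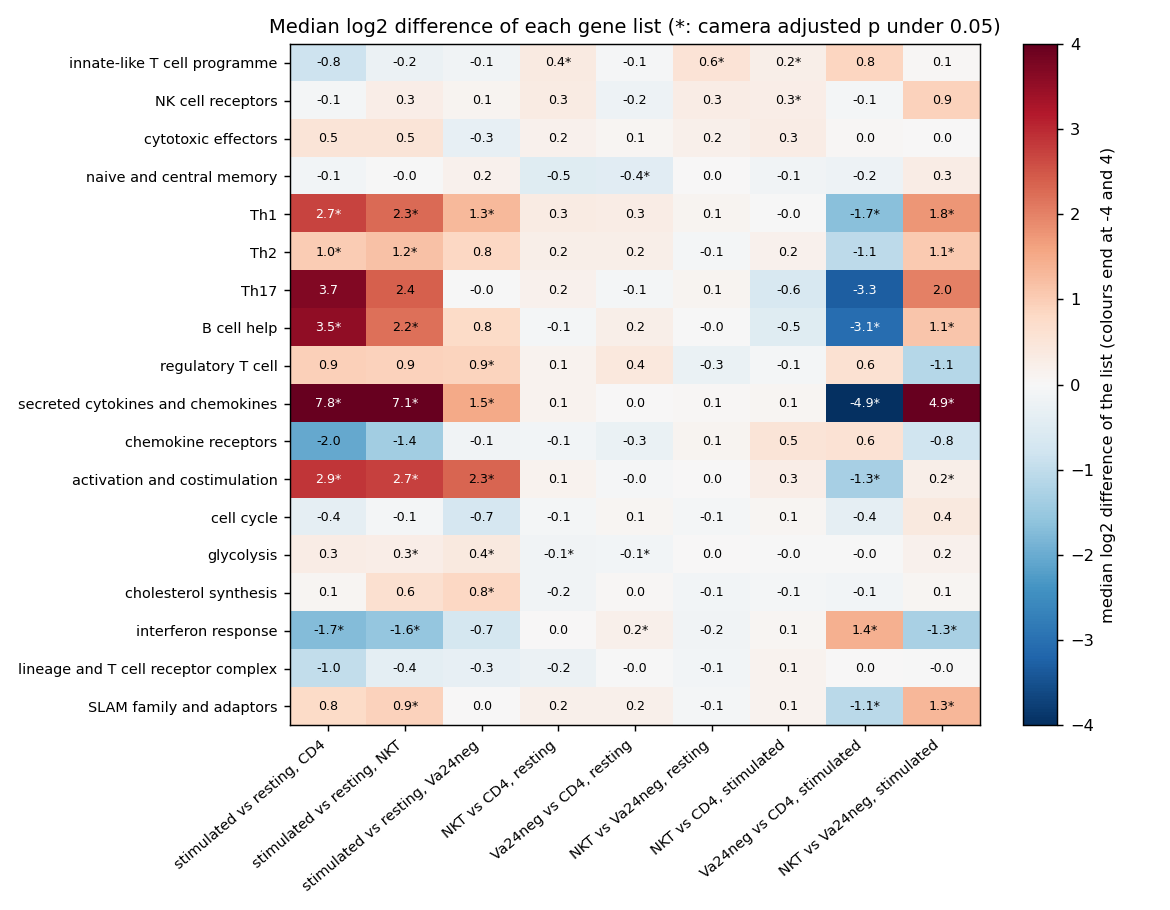
Median log2 difference of the 18 T cell gene lists in the 9 comparisons of 2 groups. Asterisks mark a camera adjusted p under 0.05 at the preset correlation.

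Differences of the stimulation response were tested directly. Between NKT and CD4 clones the differences for IL4 (-1.81, SE 0.89, adjusted p = 0.82) and TBX21 (-0.78, SE 0.74, adjusted p = 0.93) were not called. In all limma called 0 of 13634 genes for NKT minus CD4, with 836 at an unadjusted p under 0.05. For Va24neg minus CD4, 4556 genes were called, 2720 of them with a higher and 1836 with a lower response in Va24neg clones, and 3181 differed at least 2-fold. IL3 (-11.06, SE 0.23), IL22 (-8.89, SE 0.73), CD200 (-8.81, SE 0.33), IL2 (-8.28, SE 0.68) and IL21 (-8.24, SE 0.93) lagged most. C16orf54 (7.13, SE 0.52), IL16 (6.30, SE 0.20), ARHGAP45 (5.78, SE 0.39), ASB2 (5.72, SE 0.92) and ARHGDIB (5.70, SE 0.52) fell less or not at all in Va24neg clones, where CD4 clones lost them. For NKT minus Va24neg, 5055 genes were called, 2042 higher and 3013 lower, 3297 at least 2-fold. Highest were IL3 (11.34, SE 0.21), IL2 (9.56, SE 0.62), CD200 (9.06, SE 0.30), IL22 (7.98, SE 0.67) and XIRP1 (7.64, SE 0.57), and lowest IL16 (-6.31, SE 0.18), AKTIP (-5.68, SE 0.51), P2RY10 (-5.24, SE 0.43), PTPRCAP (-5.20, SE 0.43) and C16orf54 (-5.17, SE 0.47).

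Across genes the NKT and CD4 responses had a Pearson r of 0.964 and a Spearman rho of 0.943, and 7654 of the 7657 genes called in both changed in the same direction. Va24neg and CD4 responses had an r of 0.688 and a rho of 0.653, with 4617 of 4920 shared calls in the same direction. NKT and Va24neg responses had an r of 0.693 and a rho of 0.657, with 4756 of 5119. Genes that went in opposite directions numbered 303 for Va24neg against CD4, IL16 among them (-4.83 in CD4 and 1.48 in Va24neg clones), and 363 for NKT against Va24neg. Response sizes had an SD over genes of 1.63 in CD4, 1.58 in NKT and 0.997 in Va24neg clones. Increases shared by NKT and CD4 clones numbered 2750, where independent lists of the same lengths share 789.2, and shared decreases 4904 against 2135.

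**Figure D4:**
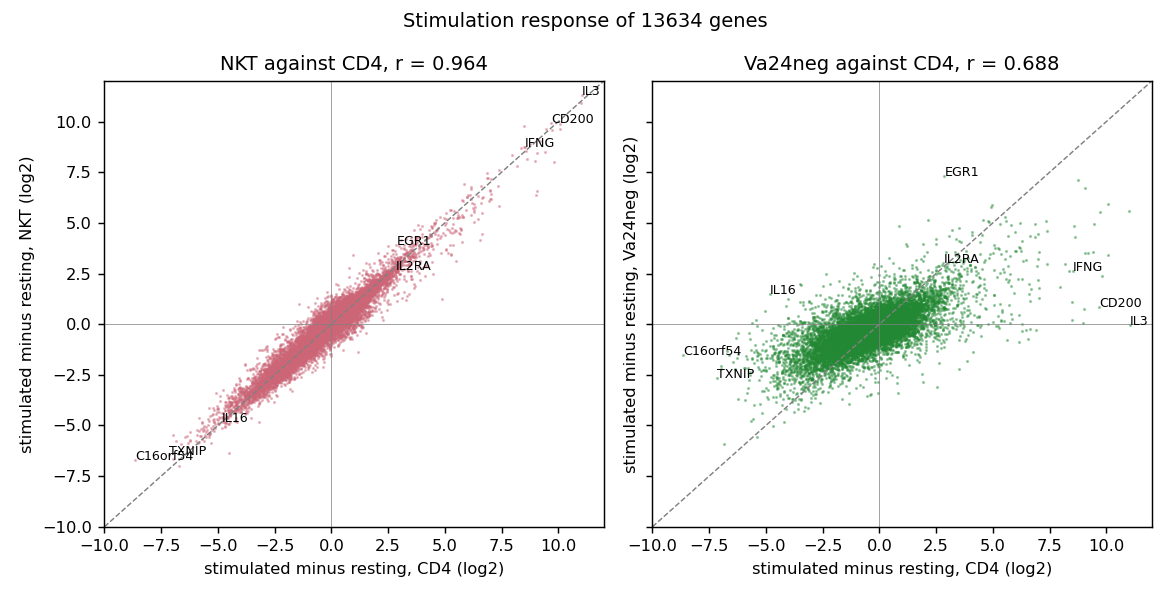
Log2 stimulation response of each gene in NKT and in Va24neg clones against the response in CD4 clones. The dashed line marks equal responses.

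Of the 33 genes higher in stimulated NKT than CD4 clones, 30 were among the 3664 higher in Va24neg clones, ZBTB16 among them, and 10 of the 22 lower genes were among 2713. Both differences use the same CD4 arrays, which alone creates overlap and correlation, and no expected overlap was computed for that. At rest the r across genes was 0.567, against 0.448 on average (-0.227 to 0.834) for unchanged groups simulated against the same arrays; the covariance was 0.068 against 0.04 (-0.00844 to 0.0679). After stimulation the r was 0.307 against a simulated 0.471 (-0.133 to 0.77), and the covariance 0.146 against 0.0517 (-0.00767 to 0.0995). With the CD4 clones divided 2 and 2 between the differences, r fell to between 0.0454 and 0.235 at rest and lay between 0.117 and 0.198 after stimulation.

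Markers of other cells were compared because irradiated feeder cells were in the cultures. The B cell score, from 15 genes on the array such as CD79A and MS4A1, was lower in stimulated Va24neg than in CD4 clones by a log2 difference of -1.03 (exact p = 0.0286, adjusted p = 0.133), and higher in stimulated NKT than Va24neg clones by 0.631 (p = 0.00476, adjusted p = 0.0889). NKT minus CD4 clones gave -0.399 (exact p = 0.00952, adjusted p = 0.0889). POU2AF1, 1 of its genes, is also in the B cell help list, and which cells expressed it was not tested. Without POU2AF1 the differences were -0.622 (exact p = 0.0286), 0.383 (exact p = 0.00952) and -0.239 (exact p = 0.0762). The red cell and platelet score differed by -0.466 between stimulated Va24neg and CD4 clones (exact p = 0.0286, adjusted p = 0.133) and by -0.247 between stimulated NKT and CD4 clones (exact p = 0.0238, adjusted p = 0.133). By exact sign-flip tests, scores changed between resting and stimulated clones by 0.101 for B cells (adjusted p = 0.687), -0.0528 for monocytes (0.6), 0.0548 for natural killer cells (0.733) and 0.273 for red cells and platelets (higher in 12 of 14 clones, p = 0.00745, adjusted p = 0.0889). The pooled B cell value joins opposite changes: 0.57 ± 0.276 in CD4 (higher in 4 of 4 clones), 0.213 ± 0.262 in NKT (4 of 6) and -0.534 ± 0.236 in Va24neg clones (lower in 4 of 4). Without POU2AF1 these were 0.142 ± 0.202, -0.0695 ± 0.254 and -0.521 ± 0.195. The red cell and platelet score changed by 0.414 ± 0.112 in CD4, 0.414 ± 0.204 in NKT and -0.0794 ± 0.296 in Va24neg clones. After correction 0 of the 28 exact permutation tests were called, with 6 at an unadjusted p under 0.05. Between Va24neg and CD4 clones, with 4 arrays each, the smallest exact p possible is 0.0286. Such differences could hardly pass the correction, so the missing calls there say little.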

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

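The tests of the 3 patterns weighed below, the B cell score without POU2AF1 and the full set of splits that part every pair were chosen after the results were seen, and the expected outcomes of the split tests were also written down after their results; the splits, the outlier limits and the differences of responses follow rules set earlier.

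The stimulated Va24neg arrays stood apart from the other stimulated arrays, with 6377 genes called against CD4 clones and a stimulation response that differed from CD4 in 4556 genes and from NKT in 5055. Array scaling alone is argued against by 6236 calls after quantile normalization. With the actin 3'/5' ratio as a covariate, 15 of 16 cytokine genes were still called lower (median -5.47 before, -5.35 after). That fit holds the group means, so the slope of the ratio comes from spread within groups. This spread was widest in resting NKT clones (6.03 ± 8.15, with A4 at 22.6). The fit therefore cannot decide on a trend with the ratio, which stays open. The B cell score was lower, not higher, in these cultures (-1.03, or -0.622 without POU2AF1), which gives no sign of more feeder B cells. It cannot settle the question, since the score was low (5.51 ± 0.192, with array medians of 6.3 ± 0.0621). The exact test did not call the difference of the score (p = 0.0286, adjusted p = 0.133). With 4 arrays per group that is the smallest exact p possible, so the missing call carries no weight. Resting arrays under a stimulated label are argued against by 14 of 19 activation genes that rose. A batch of culture or array processing stays open as well. In 4 of 4 stimulated Va24neg arrays the actin 3'/5' ratio (2.04 ± 0.352) lay outside the range of the other stimulated arrays (4.75 ± 0.17 in CD4 and 4.8 ± 0.871 in NKT clones). The ribosomal RNA probes (highest 9.65, others from 9.72) and spike-in controls of the 4 arrays also lay below the others, while their GAPDH ratios lay inside. The actin ratio already differed between resting Va24neg (3.9 ± 0.419) and CD4 clones (2.54 ± 0.197). Batch and cell type cannot be told apart. The cell type itself, which the design names, also stays open and was not tested apart from such a batch.

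CD4 clone A1 held ZBTB16 far above the other stimulated CD4 clones (a gap of 0.887 of the range), and at rest ZBTB16 reached 101 percent of the NKT mean. A mislabelled NKT or Va24neg clone of this study is argued against by the probe set annotated to IL23A, which was at 1.05 and 1.89 in its 2 arrays and at 5569 or more in each of the 20 NKT and Va24neg arrays. This probe set was first picked with A1 counted among the CD4 clones. In the limma fit without A1 it was also called between resting NKT and CD4 clones (9.54, adjusted p = 3.9e-16). NKT cells mixed into the resting culture are argued against by the same 1.05, where that share of NKT RNA would have brought about 14100. No technical explanation beyond these was tested, and a conventional clone that expresses PLZF may be what the label says. Without this clone, NKT exceeded CD4 clones at rest in ZBTB16 by 3.34 (adjusted p = 1.4e-05) and Va24neg clones by 2.44 (adjusted p = 0.0073), against 2.44 (adjusted p = 0.32) and 1.62 (adjusted p = 1) with it. Since the clone was singled out by its ZBTB16 level, its removal raises these differences by construction and is no independent evidence for them.

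The probe set annotated to IL23A separated all 8 CD4 arrays (at most 7.51) from all 20 NKT and Va24neg arrays (5569 to 25910). A transcript of IL23A is argued against by another probe set of that gene, which rose by 5.92 ± 0.429 in NKT and 5.62 ± 0.211 in CD4 clones while the first changed by 0.241 ± 0.412 and 0.132 ± 0.141 (smallest gap in an NKT clone 4.85). In Va24neg clones both responses were small (1.32 ± 0.383 and 0.884 ± 0.0893, smallest gap 0.223), but at rest the other probe set was at 383 ± 82.6 in them against 336 ± 15.3 in CD4 clones, where the first was at 13000 ± 1410 against 2.37 ± 0.892. Whether the first probe set measures a T cell receptor segment used by both kinds of CD1d-restricted clone stays open. A further probe set annotated to IL23A was at 7390 or more in both states of 1 Va24neg clone. In all other clones it was at most 109. Another, annotated to IL23A and to the T cell receptor segment TRBV19, had group means from 29.4 to 86.6 and lacked the separation. Neither settles what the first probe set measures. That 14 of 14 clones kept their side in both states follows from the separation itself and decides nothing, and probe sequences were not used here.

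Response differences that passed their test are given once more as single values. Genes with a lower response in Va24neg than CD4 clones were IL3 (-11.06), IL22 (-8.89), CD200 (-8.81), IL2 (-8.28), IL21 (-8.24), IL4 (-7.41), IFNG (-5.88) and TBX21 (-2.82), and genes with a higher one C16orf54 (7.13), IL16 (6.30), ARHGAP45 (5.78), ASB2 (5.72) and ARHGDIB (5.70). The list medians of the same difference were -5.21 for secreted cytokines, -2.77 for B cell help, -1.99 for Th1, -1.44 for the SLAM family, -1.16 for activation, -1.11 for Th2 and 1.15 for the interferon response. Of these, with an estimated correlation only cytokines (adjusted p = 0.000946) and B cell help (adjusted p = 0.034) were called, while the SLAM family (0.071), activation (0.0601), Th2 (0.563), Th1 (0.567) and the interferon response (0.611) were not. For NKT minus Va24neg clones the genes were IL3 (11.34), IL2 (9.56), CD200 (9.06), IL22 (7.98), XIRP1 (7.64), IFNG (6.11), IL4 (5.60) and TBX21 (2.04) upward and IL16 (-6.31), AKTIP (-5.68), P2RY10 (-5.24), PTPRCAP (-5.20) and C16orf54 (-5.17) downward. Its lists were secreted cytokines (4.78), Th1 (1.75), Th2 (1.29), the SLAM family (1.29), B cell help (1.02), activation (0.597) and the interferon response (-0.954). With an estimated correlation, cytokines (adjusted p = 0.000946) and the SLAM family (0.0472) were called and activation (0.0833), B cell help (0.0937), Th2 (0.563), Th1 (0.567) and the interferon response (0.611) were not. Between NKT and CD4 clones, 3 lists passed at the preset correlation: B cell help (-0.548, adjusted p = 0.11 with an estimated correlation), the lineage and T cell receptor complex list (0.416, adjusted p = 0.53 with an estimated correlation) and glycolysis (0.0295, mean 0.22, adjusted p = 0.563 with an estimated correlation).

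Dixon's limit marked 12 of 120 groups of values, where chance marks about 1 in 20. NKT clone A4 at rest accounts for 4 of them, with the highest actin (0.747) and GAPDH 3'/5' ratio (0.806), ribosomal RNA probes (0.777) and red cell and platelet score (0.676). Low-intensity CD8 genes account for 3: CD8A in stimulated NKT clone A14 (0.708), and CD8B in resting Va24neg clone B3 (0.854) and stimulated NKT clone B9 (0.715). TBX21 was lowest in stimulated CD4 clone B3 (0.938), and MKI67 was highest in resting Va24neg clone A7 (0.841). The spike-in controls were highest in stimulated CD4 clone A1 (0.836), and the natural killer score was highest in resting Va24neg clone B3 (0.932).

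Other splits of the same arrays show how many genes other groupings call. Where 100 splits are given, they are a sample of 462 possible splits for the NKT response and of 210 for the other comparisons. The smallest possible share is 1 of the splits run. The split tests were not corrected for their number, so a share under 1 in 20 does not exclude chance. For stimulated against resting CD4 clones 1 of 35 splits, the real one, gave as many genes as 8325 (highest other 3), for NKT 1 of 100 gave 9042 (highest other 6765, which exchanged 1 array of each state), and for Va24neg 1 of 35 gave 5948 (highest other 44). These splits ignore that the arrays are paired by clone. Among the 32 splits of the NKT arrays that part every pair, only the real one gave 9042 (highest other 6724, with 1 pair exchanged). CD4 and Va24neg clones have 8 such splits each, too few for a share under 1 in 20 (highest other 0 by limma for both, against 8325 and 5948). The real split alone reached its count for stimulated Va24neg against CD4 (1 of 35 gave 6377, highest other 5). The same was true for stimulated NKT against Va24neg (1 of 100 gave 6692, highest other 4222, which kept the 4 Va24neg clones together). It also held for the response differences of 4556 (1 of 35, highest other 1) and 5055 (1 of 100, highest other 2145, with the same 4 clones together). The share was above 1 in 20 for the count of stimulated NKT against CD4, where 11 of 100 splits gave 55 or more. The highest, 1061, put NKT clones A1 and A4 with the CD4 clones, which points to a structure among these arrays that was not examined further. At rest, 18 of 100 splits gave as many as the 1 gene of NKT against CD4 (highest other 16), 4 of 35 as many as the 1 gene of Va24neg against CD4 (highest other 1), and 100 of 100 as many as the 0 genes of NKT against Va24neg (highest other 10; 703 at an unadjusted p under 0.05 by limma). For the response difference of NKT and CD4, with 0 genes by limma and 836 at an unadjusted p under 0.05, it was 100 of 100 (highest other 43). Any split calls at least 0 genes, so both shares of 100 of 100 were certain and decide nothing. The counts of 1 at rest carry no weight as counts. The gene itself, the probe set of IL23A, had an adjusted p of 6.2e-19 by limma against CD4 in NKT clones.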

How the results depend on the processing

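Alternatives were planned before the results were seen, except the actin covariate and the fit without the resting array of NKT clone A4, chosen after seeing the data. Of 354 counts of genes 305 stayed within 1.5 times, 28 grew more and 21 shrank more. Of 19167 values of named genes 821 lost and 25 gained a call and 5 changed sign. For correlations, 163 of 163 moved by less than their spread between clones, estimated from the fits that leave out 1 clone. For the NKT and Va24neg differences from CD4 that spread was 0.55 around an r of 0.567 at rest and 0.281 around 0.307 after stimulation. Limits that wide could hardly be passed and say nothing of stability there. For the correlations between stimulation responses the spread was 0.0336 to 0.0756. Call counts at rest were small. For NKT against CD4, where 1 gene was called, they were 0 with pseudocount 1 (limma), 2 with the 70th percentile filter, 3 with the mean of probe sets, 2 with a trended robust prior and 2 without the array of NKT clone A4. For Va24neg against CD4 they were 2 with quantile normalization, 0 with pseudocount 1, 2 with pseudocount 64, 20 in donor B only and 5 with only the arrays compared, and for NKT against Va24neg 1 with pseudocount 1 and 6 in donor B only. The 55 genes of stimulated NKT against CD4 became 24 with quantile normalization, 21 without a filter, 138 with the 70th percentile filter, 29 with the most variable probe set, 5 in donor A only, 2 with only the arrays compared, 100 with the trended robust prior and 94 with the actin covariate. Donor A only, with fewer arrays, gave 3447 for the Va24neg response, 3991 for stimulated Va24neg against CD4, and 1895 and 2668 for the differences of the Va24neg response from CD4 and NKT. Donor B only gave 3324 for the last. ZBTB16 fell in stimulated CD4 clones by a difference that became called at -1.57 with pseudocount 1, -1.26 in donor B only, and -1.45 with the 70th percentile filter, other probe set choices and clone as a random (adjusted p = 0.023) or fixed block (adjusted p = 0.00018). In Va24neg clones it was called at -0.80 with the fixed block and with only the arrays compared. ZBTB16 in stimulated NKT against CD4 was not called in donor A only (2.69, adjusted p = 0.58) or with only the arrays compared (3.51, adjusted p = 0.32), nor in Va24neg against CD4 in donor A only (1.97, adjusted p = 0.18). NKT against Va24neg was called in donor B only (2.03) and with only the arrays compared (1.28). With clone as a random block, called lists became NK cell receptors in resting NKT against Va24neg (adjusted p = 0.0427) and the lineage list in stimulated NKT against CD4 (adjusted p = 0.0427), each with adjusted p = 0.567 with an estimated correlation. The fixed block also gave a call to the response of CD4 (-1.90, adjusted p = 0.031) and GATA3 (0.70, adjusted p = 0.0076, and 0.031 with the random block) in Va24neg clones and to the KLRB1 response of Va24neg minus CD4 (1.84, adjusted p = 0.0012) and NKT minus Va24neg (-1.24, adjusted p = 0.0081). It ended those of CXCR5 in Va24neg clones and of CSF1R, IL17F, IL1R1 and IL7R for Va24neg minus CD4. Besides these and the values given beside their results, the blocks changed no call of a named gene or list. Lists called numbered 14 with an estimated correlation and 102 with fry, against 58, and the red cell and platelet score rose by 0.398 after quantile normalization (adjusted p = 0.0205). Signs changed for IGHM (0.08) and CIITA (0.73) with the most variable probe set, GATA3 in NKT clones (-0.01) with quantile normalization, and IL23A (-0.09 for resting NKT, -4.17 for stimulated Va24neg, both against CD4) with pseudocount 1, which makes another probe set represent the gene.

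Leaving out each clone in turn, NKT against CD4 at rest called 1 to 8 genes (8 without CD4 clone A1, 4 without NKT clone A1, 2 without CD4 clone B3 or NKT clone A4). Va24neg against CD4 called 1 to 5 (5 without CD4 clone A1, 2 without NKT clone A14, NKT clone A22 or Va24neg clone A4), and NKT against Va24neg 0 to 2 by limma (2 without NKT clone B9). The NKT and CD4 responses differed in 0 to 1 (1 without NKT clone A4). Stimulated NKT against CD4 called 10 to 304: 304 without NKT A1, 10 without CD4 A4, 14 without CD4 B2, 18 without NKT B1, 23 without NKT A22, 32 without CD4 B3, and 32, 33, 28 and 33 without Va24neg A4, A7, B3 and B4. ZBTB16 ranged from 1.98 to 3.34 (NKT against CD4) and 1.21 to 2.44 (Va24neg against CD4) at rest, each highest and called without CD4 A1. For stimulated clones it ranged from 2.89 (adjusted p = 0.067, without CD4 A4) to 4.31 for NKT against CD4 and 1.76 to 3.06 for Va24neg against CD4. The range was 0.89 to 1.39 for stimulated NKT against Va24neg (1.25, called, without CD4 A1) and -1.71 to -1.32 for stimulated against resting CD4. The red cell and platelet score ranged from 0.245 to 0.329 (adjusted p = 0.0205 without Va24neg A4).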

Other observations

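Fits without CD4 clone A1 were planned; the genes described from them were chosen after the result was seen. TBC1D4, which controls glucose transporter traffic, was then lower in resting NKT than CD4 clones (-3.57, SE 0.59, adjusted p = 0.02; -2.83 with the clone), as were the actin regulator FMNL2 (-4.35, SE 0.75, adjusted p = 0.022) and the histamine receptor HRH4 (-2.25, SE 0.43, adjusted p = 0.05, rounded up). IER5 (0.86, SE 0.15, adjusted p = 0.022), DISP3 (1.58, SE 0.28, adjusted p = 0.022) and LINC02910 (2.56, SE 0.49, adjusted p = 0.05) were higher. In resting Va24neg against CD4 clones HRH4 was lower (-2.56, SE 0.45, adjusted p = 0.034), and the lactonase PON2 (2.36, SE 0.42, adjusted p = 0.034) and APBA2 (1.26, SE 0.22, adjusted p = 0.034) were higher. None of these genes was called with all 14 clones.

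Genes with several probe sets sometimes held opposite calls. Of the genes called in stimulated against resting clones and measured by several probe sets, a further probe set was called in the opposite direction for 434 of 5477 in CD4, 565 of 5881 in NKT and 176 of 3868 in Va24neg clones.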
